A study of Mus musculus with 2 samples.

How the data were processed

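Lung cells of control mice and of mice with a conditional knockout of Foxf2 were compared, with 1 single-cell library per group. Per the labels, lungs were minced, digested with Dispase, DNase I and collagenase, dissociated mechanically and treated with red cell lysis buffer. Leukocytes were then depleted with an anti-CD45 antibody and magnetic beads, and libraries were made with a droplet kit that reads transcripts from the 5' end. The deposited values are a count of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. They were made with Cell Ranger 7.0.1 against mm10 according to the submitters' processing notes, whereas the file headers name Cell Ranger 7.1.0. Each table listed 32285 genes, of which 32235 matched the annotation by identifier. Every barcode had at least 500 UMIs, so barcodes with fewer had been left out of the deposited values. The Cre driver, the deleted part of Foxf2 and the ages, sexes, exposures and numbers of animals are not given in the sources used here.

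Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. In the control library 3936 barcodes were under the UMI minimum, 123 under the gene minimum and 223 over the mitochondrial limit. In the cKO library the numbers were 4411, 117 and 212. Doublets were called per library with Scrublet in scanpy 1.11.5 at an expected 10% and removed, 337 (2.83%) in the control and 216 (1.75%) in the cKO library. The kept cells held 117889722 UMIs in the control and 114241354 in the cKO library.

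Both libraries were clustered together without batch correction. UMIs were scaled to cell totals and log-transformed, and 2000 variable genes, 40 principal components and 20 neighbours were used with Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Foxf2, sex-linked, mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes were left out of the variable genes. Each of the 40 clusters was named from fixed markers of 27 cell classes when at least 3 markers of the class were at 50 CPM or more and at least 2-fold above all other cells. Clusters led by markers of another class, or shallow clusters with none of the class's markers among their 10 top genes, stayed unnamed. Of the 40 clusters, 35 were named and 5 were left out of the comparisons of genes. Because genes such as Pdgfrb, Kcnj8, Abcc9 and Acta2 served as markers, their level in a class as such is no result, while their ratio between libraries within the class is.

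UMIs were summed over the cells of each class and library and divided by the class total to give UMIs per 1000000 UMIs (CPM), with exact Poisson 95% intervals. Log2 ratios are cKO over control with the exact conditional binomial interval of 2 Poisson counts, and shares of cells have exact Clopper-Pearson intervals. No p-value was computed, since cells of 1 library are not replicates. Gene comparisons covered the 14 classes with at least 100 cells in each library. The other-class median of a gene is over the remaining compared classes where it was measured. The median log2 ratio of each of 25 fixed gene lists, over members with at least 20 UMIs and without Foxf2, was placed among 10000 random lists of the same size matched on level, as a description of these libraries.

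Genes were named by a fixed rule: the 10 highest and 10 lowest log2 ratios in pericyte-like cells, 5 and 5 in the capillary and other mesenchymal classes, and up to 4 members of each list with the largest ratio. Eligible genes had at least 50 CPM in the library where they were higher, at least 50 UMIs in all, and at least 10% of the level of the gene's highest class, a limit meant to reduce free RNA. A level of 0 was set to a floor of 3 UMIs. Some genes that met the rule are not reported here. Other genes named, and the search by chromosome position in windows of 2 Mb, were chosen after the values were seen. The filters, markers, lists, naming rule and the alternatives not named as later were chosen before the data were examined.

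Alternatives were TMM factors (edgeR 4.0.16) and DESeq2 1.42.0 size factors, the mean of each cell's CPM, thinning to 1 depth, other minimums for list members, at most 5% mitochondrial UMIs, at least 2000 UMIs, doublets kept, resolutions 0.5 and 2, each library clustered alone, and pericyte-like cells with UMIs of at least 3 markers. Chosen after seeing the data were the largest pericyte-like cluster alone, leaving out the 1% of cells with most UMIs of a gene, and leaving out genes of the chromosome 5 segment. The interval and list procedures were tested on simulated data, where 96.2% of the intervals of 11531 genes without a difference held the true value, as did at least 98% for 4 planted folds. The simulated counts were Poisson, as the intervals assume, so uneven counts between cells were not covered. Of simulated lists, 3% without a shift and 99% with a log2 shift of 0.3 fell outside the central 95% of random lists. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.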

Results

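Single-cell RNA sequencing was done on lung cells depleted of CD45-positive leukocytes, from control mice and from mice with a conditional knockout (cKO) of Foxf2, a forkhead transcription factor of lung mesenchyme. There was 1 library per group, so no difference between the libraries has a replicate check, and none was tested. The control library held 16213 barcodes with 128262168 unique molecular identifiers (UMIs) and a median of 5197 UMIs per barcode. The cKO library held 17085 barcodes with 122525548 UMIs and a median of 3577. After filtering, 11594 control cells with a median of 8298.5 UMIs and 12129 cKO cells with a median of 7407 UMIs were kept. Levels are UMIs per 1000000 UMIs (CPM), summed over the cells of a class, and ratios are cKO over control. All intervals are exact 95% intervals that cover counting error only. The number of animals per library, their age, their sex and their exposure are not given in the sources used here.

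The first question was whether Foxf2 itself differed in the cells of the cKO library, which checks the labels. Foxf2 (ENSMUSG00000038402, chromosome 13, 31625816 to 31631403, mm10) was 4.35-fold lower in pericyte-like cells of the cKO library, the capillary mural cells named in the study's title. It stood at 191 CPM (176 to 207) in the control library and 44.0 CPM (37.1 to 51.8) in the cKO library, from 585 and 144 UMIs, a log2 ratio of -2.12 (-2.39 to -1.86). When each library was clustered alone, the log2 ratio was -1.67. The other Foxf2-expressing classes differed far less. Foxf2 was at 114 and 108 CPM in alveolar fibroblast-like cells, 249 and 209 CPM in the class with both myofibroblast and smooth muscle markers, 78.2 and 63.1 CPM in smooth muscle-like cells, and 37.7 and 25.6 CPM in adventitial fibroblast-like cells. The smooth muscle-like class pools 5 clusters, and Foxf2 was at 12.8 and 12.03 CPM in the largest of them. Foxf2 UMIs were seen in 55.3% (50.4 to 60.1) of control and 20.1% (16.5 to 24.1) of cKO pericyte-like cells, at median depths of 6022 and 6085.5 UMIs. The background share in alveolar type 2-like cells was 2.16% and 2.08%, at median depths of 15324 and 16439 UMIs. Thinned to 1427 UMIs per cell, with 44 shallower cells left out in each library, the shares in pericyte-like cells were 25.7% (21.4 to 30.4) and 7.84% (5.43 to 10.9).

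Foxf2 was at most 10 CPM in the endothelial-like, epithelial-like and mesothelial-like classes of both libraries. It stood at 9.18 and 6.10 CPM in general capillary-like cells, 4.37 and 4.69 in aerocyte-like cells, 3.25 and 9.72 in arterial-like cells, 8.80 and 3.28 in venous-like cells, and 3.73 and 4.11 in lymphatic-like cells. It stood at 9.70 and 7.93 CPM in mesothelial-like cells, 4.25 and 4.43 in alveolar type 1-like cells, 2.12 and 1.74 in alveolar type 2-like cells, 7.95 and 3.41 in club-like cells, and 1.98 and 5.38 in ciliated-like cells. Chondrocyte-like cells held 16 UMIs among 100 control cells and 0 among 16 cKO cells. Schwann-like cells held 3 and 0 UMIs, and erythroid-like cells 1 and 2. Foxf1, the closest relative of Foxf2, was at 306 (287 to 326) and 342 (322 to 363) CPM in pericyte-like cells and at 633 and 710 CPM in general capillary-like cells. In the other compared classes with at least 100 CPM of Foxf1 in either library, its log2 ratio lay between -0.25 in mesothelial-like cells and 0.18 in venous-like cells. The deleted part of Foxf2 is not given in the sources used here, and a UMI from outside that part would count in both libraries. Foxf2 has 2 annotated exons.

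**Figure D1:**
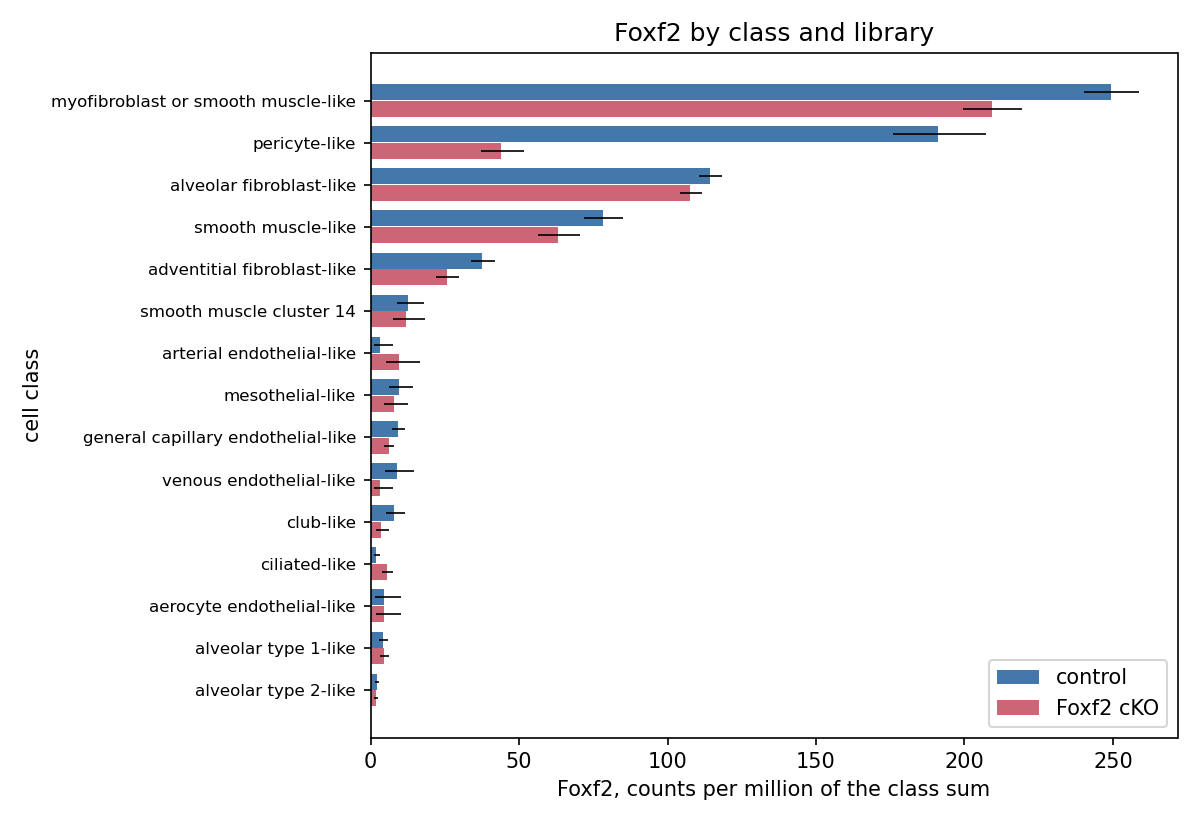
Foxf2 in CPM (horizontal axis) by class (vertical axis) in the control and Foxf2 cKO libraries, 1 library each, with exact Poisson 95% intervals as bars. Pericyte-like cells stood at 191 and 44.0 CPM, and alveolar fibroblast-like cells at 114 and 108 CPM.

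The next question was which cell populations each library held. Pericyte-like cells made up a like share of both libraries, 3.67% (3.33 to 4.02) of control cells and 3.73% (3.40 to 4.08) of cKO cells. General capillary-like cells were at 6.78% (6.33 to 7.25) and 6.41% (5.98 to 6.87), and aerocyte-like cells, the capillary endothelium of gas exchange, at 1.92% (1.68 to 2.19) and 1.94% (1.70 to 2.20). Adventitial fibroblast-like cells were at 7.44% and 4.96%, the myofibroblast and smooth muscle class at 6.61% and 4.23%, smooth muscle-like cells at 6.21% and 4.62%, and alveolar type 2-like cells at 9.97% and 11.5%. Digestion and CD45 depletion can set these shares. So can the clusters left unnamed, which held 12.3% of control and 22.2% of cKO cells at median depths of 1491 and 1492 UMIs. An unnamed cluster with the capillary markers Car4, Apln and Tmem100 among its top genes held 446 control and 904 cKO cells. It was left unnamed because aerocyte and general capillary markers were mixed in it. The capillary shares above, and the gene comparisons, are without these cells. Finer clustering placed the aerocyte-like share at 3.08% and 3.91%, and coarser clustering the general capillary-like share at 13.7% and 18.2%.

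In pericyte-like cells, the question was what else differed beside Foxf2. Pdgfrb, the receptor that recruits pericytes to vessels, was 2.85-fold higher in the cKO library, at 1012 and 2884 CPM with a log2 ratio of 1.51 (1.45 to 1.57). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 572 and 1122 CPM, and Gdf15, a stress-induced cytokine gene, at 54.6 and 110 CPM. Both genes and Pdgfrb were also higher in the other classes, with median log2 ratios there of 0.70, 0.79 and 1.21. Some of the genes named by size had a ratio in pericyte-like cells outside the range of the other classes where they were measured. Among those lower in the cKO library, Impdh1, an enzyme of guanine nucleotide synthesis, was at 103 and 45.2 CPM (log2 ratio -1.19, against a median of 0.10 and a minimum of -0.35 in the other classes). Dach1, a transcription factor gene (-1.15 against a minimum of -1.05), and the X-linked protocadherin gene Pcdh19 (-1.45 against a minimum of -0.72 over 4 classes) also lay outside that range. Cadps2 (-1.17) and Sult1a1 (-1.14) were lower still in another class. Among those higher, Prss23 was at 30.4 and 68.7 CPM (1.18 against a maximum of 0.77), and Ccn5 at 32.7 and 66.3 CPM (1.02 against a maximum of 0.44 over 5 classes). Tnfrsf12a, the receptor of TWEAK, was at 50.3 and 142 CPM (1.49), Ass1, the argininosuccinate synthase gene, at 53.3 and 142 CPM (1.42), and Ak1 at 54.3 and 124 CPM (1.19), but other classes reached 1.76, 1.76 and 1.34. Vgll3 (1.01) and Map3k7cl (1.00) were among the 10 highest too.

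These genes were named by size among 4091 eligible genes. With each library clustered alone, the log2 ratios of Prss23, Ccn5 and Map3k7cl were -1.14, -1.58 and -1.18. Muc5b and Tff2, mucus genes of airway epithelium, also led the lower genes, but 1 cell held 151 of the 154 control UMIs of Muc5b and 374 of the 378 of Tff2, and 1 cKO cell held 126 of the 192 UMIs of Cxcl10.

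**Figure D2:**
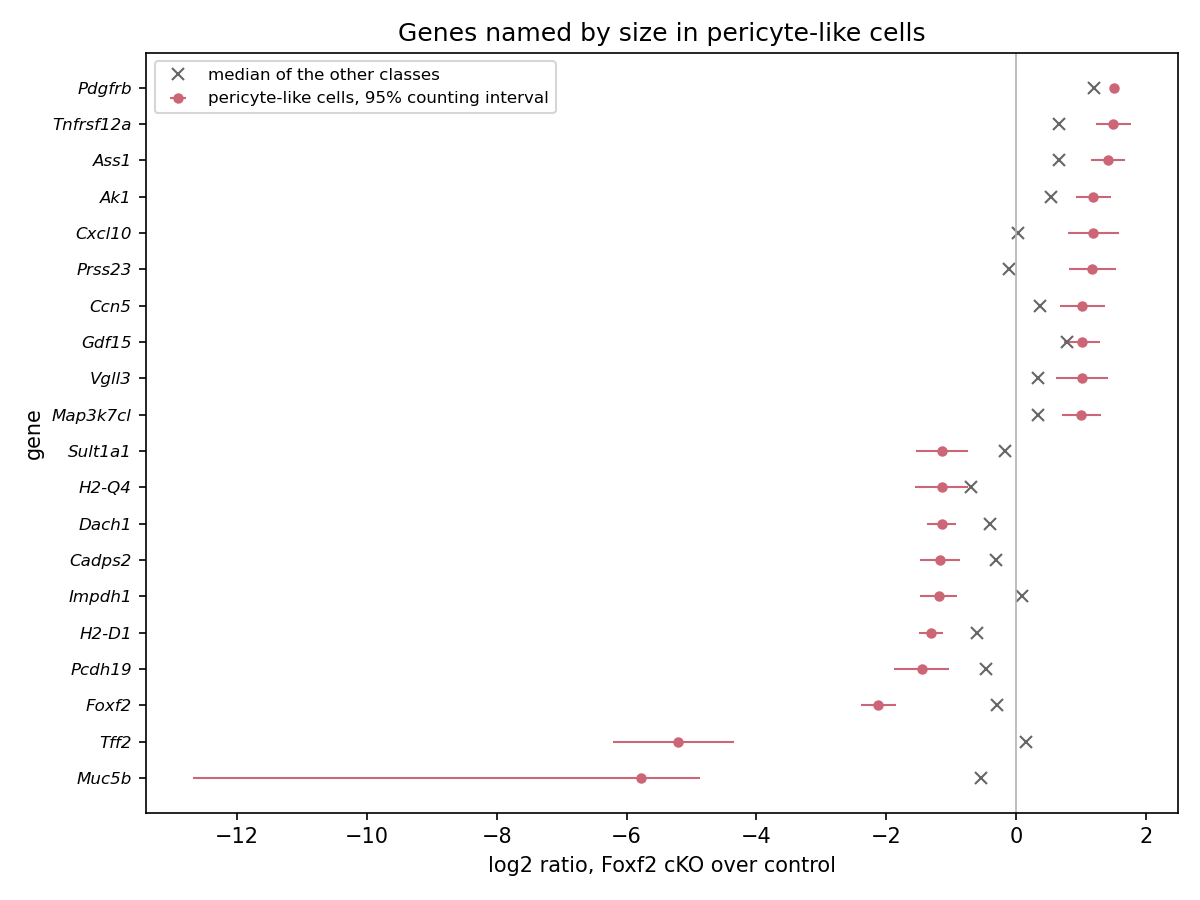
Log2 ratio of cKO over control (horizontal axis) of the 10 genes highest and 10 lowest by size in pericyte-like cells (vertical axis), with 95% counting intervals as bars and the median over the other classes as crosses, 1 library per group. Foxf2 stood at -2.12 against -0.29 in the other classes, and Pdgfrb at 1.51 against 1.21.

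As a list, pericyte identity genes differed little in the cKO library, while contractile genes were higher and genes for vascular tone lower. Identity genes such as Cox4i2 and Kcnj8 also served to name these cells, which favours a like level in both libraries. Single marker genes went both ways, with Pdgfrb higher and Kcnj8 lower. The median log2 ratio of the 15 pericyte identity genes was -0.04 (percentile 16.1 among 10000 random lists matched on level). Cox4i2 (2509 and 2474 CPM), Higd1b and Ndufa4l2 were nearly alike, whereas the ATP-sensitive potassium channel genes Kcnj8 (60.1 and 30.5 CPM) and Abcc9 (47.4 and 35.7 CPM) and the vitronectin gene Vtn (80.4 and 46.1 CPM) were lower. Their log2 ratios of -0.98, -0.41 and -0.80 stood against medians of -0.35, -0.85 and -1.67 in the other classes, so only Kcnj8 was lower than there. Of 15 contractile genes, 13 were higher, with a median of 0.34 (percentile 100). Acta2, smooth muscle actin, was at 2622 and 3891 CPM, Tagln at 1826 and 2846, Actg2 at 207 and 351, and Cnn1, calponin, at 20.9 and 46.7. Cnn1 was at a log2 ratio of -0.10 with cells thinned to 1 depth. Contractile medians were 0.28 in the myofibroblast and smooth muscle class, 0.34 in adventitial fibroblast-like, 0.14 in alveolar fibroblast-like and -0.00 in smooth muscle-like cells, with 0.13 in their largest cluster. In the endothelial-like, epithelial-like and mesothelial-like classes they lay between -0.24 in club-like and 1.32 in arterial-like cells. With each library clustered alone, the contractile median in pericyte-like cells was 0.04 and the log2 ratio of Actg2 0.018. Of the 18 measured genes of vasoregulation and ion channels, 14 were lower, with a median of -0.23 (percentile 0.12). They included the endothelin receptor gene Ednra (462 and 330 CPM), the guanylate cyclase genes Gucy1a1 and Gucy1b1 (log2 ratio -0.23 each) and Rgs4 (98.4 and 73.0 CPM).

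Other programmes also differed in pericyte-like cells. The 17 p53 targets had a median of 0.51 (percentile 100) with 16 higher, and the 17 TGF-beta and BMP targets 0.26 (percentile 100) with 12 higher, among them Ltbp2 (557 and 738 CPM), Ccn1 (888 and 1147 CPM) and Ccn2 (508 and 654 CPM). The TGF-beta and BMP median and the log2 ratio of Ccn2 were both -0.10 with each library clustered alone. The 13 antigen presentation genes had a median of -0.50 (percentile 0) with 9 lower, led by the class I genes H2-D1 (253 and 102 CPM) and H2-K1 (128 and 59.8 CPM). Cd74, the class II invariant chain, went the other way, at 20.9 and 52.2 CPM, a log2 ratio of 1.32 that was 0.50 with called doublets kept. All 24 measured cell cycle genes were lower, with a median of -0.30 (percentile 0.01), but that median was 0.99 with each library clustered alone. The 8 myofibroblast identity genes had a median of -0.94 (percentile 0), with Wnt5a at 37.3 and 18.9 CPM and Enpp2 at 84.3 and 45.2 CPM. With each library clustered alone, the median of this list and the log2 ratio of Wnt5a were both -0.076, and Tgfbi and Pdgfra turned from -2.30 and -1.32 to 0.64 and 1.38. The myofibroblast and smooth muscle class was itself at 6.61% and 4.23% of cells. The 19 inflammation and leukocyte adhesion genes had a median of 0.15 (percentile 98.8) and went both ways, with the chemokine gene Ccl2 at 156 and 73.6 CPM and the NF-kappaB inhibitor Nfkbia at 300.0 and 413 CPM. Their median was -0.15 with called doublets kept and -0.13 with each library clustered alone.

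UMIs of alveolar epithelial genes in pericyte-like cells were also higher in the cKO library. The surfactant and lamellar body list had a median of 0.59 (percentile 100) there, which was 0.11 with called doublets kept. In general capillary-like cells it was 0.00, but 0.33 to 0.78 under 4 of the alternatives. Sftpc, a product of alveolar type 2 cells, was at 1222 and 2614 CPM in pericyte-like cells. The alveolar type 1 and transitional epithelium list had a median of 0.25 (percentile 99.9). The remaining lists had medians of -0.23 for alveolar fibroblast identity (percentile 3.44), -0.23 for capillary endothelial identity (4.46), -0.16 for basement membrane (2.84), -0.15 for lung mesenchyme transcription factors (2.11), -0.13 for angiogenic and tip endothelial genes (10.9) and -0.10 for mitochondrially encoded genes (8.21). With the mean of each cell's CPM, the capillary identity median was 0.16, the alveolar fibroblast one 0.052 and the mitochondrial one -0.001. Medians were -0.03 for interferon response (60.3), 0.05 for glycolysis and hypoxia (80.6), 0.05 for oxidative stress (83.8), 0.06 for fibrillar collagen and matrix (73.2), 0.11 for immediate early genes of dissociation (96.1) and 0.18 for Notch targets (95.7). The immediate early median was -0.026, the angiogenic one 0.048, the Notch one -0.28 and the basement membrane one -0.046 with each library clustered alone. With cells thinned to 1 depth the basement membrane median was -0.26.

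**Figure D3:**
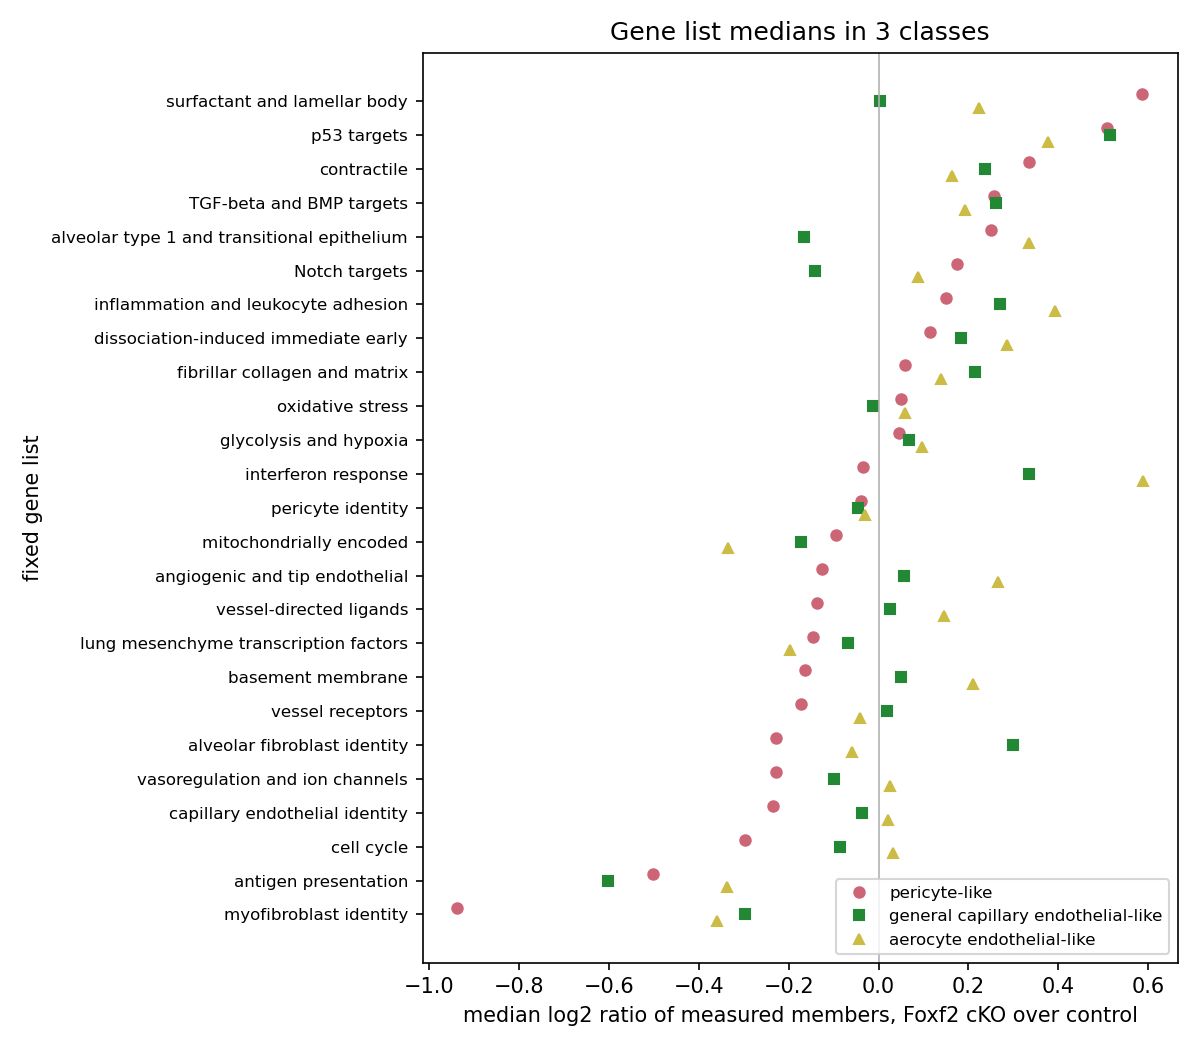
Median log2 ratio of cKO over control (horizontal axis) of the measured members of each fixed gene list (vertical axis) in pericyte-like, general capillary-like and aerocyte-like cells, 1 library per group. The p53 targets stood at 0.51, 0.52 and 0.38, and antigen presentation genes at -0.50, -0.60 and -0.34.

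The title of the series names signalling between pericytes and endothelium, so vessel-directed ligands of pericyte-like cells were set beside receptors of capillary endothelial cells. Among ligands with at least 50 CPM, the genes of both angiopoietins and of hepatocyte growth factor were lower in cKO pericyte-like cells. Angpt1, which activates the endothelial receptor Tek, was at 338 and 232 CPM (log2 ratio -0.54, -0.68 to -0.40) against a median of -0.02 in the other classes. Angpt2 was at 62.4 and 35.1 CPM (-0.83, -1.18 to -0.49) and Hgf at 86.9 and 54.4 CPM (-0.68, -0.96 to -0.40). Thbs1, an anti-angiogenic matrix protein gene, was higher at 281 and 440 CPM (0.65), as were Pgf at 84.3 and 120 CPM (0.51, against 0.57 in the other classes) and Slit3 at 128 and 175 CPM (0.45). Slit3 was at -1.25 and Thbs1 at 0.019 with each library clustered alone. The 42 measured ligands had a median of -0.14 (percentile 13.1), with 25 lower, and a median of 0.081 with the mean of each cell's CPM. The 40 measured vessel receptors had a median of -0.17 (percentile 0.97) in pericyte-like cells. That median was -0.059 with cells thinned to 1 depth and -0.08 with each library clustered alone. Among receptors there, Bmpr1a (-0.41) and Tgfbr2 (-0.41) were lower and Flt1 was at 120 and 186 CPM (0.63). These abundant members were chosen after their values were seen.

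In the endothelial-like cells, the receptor lists as a whole did not stand apart. The median was 0.02 (percentile 68.4) over 41 receptors in general capillary-like cells and -0.04 (percentile 16.5, or -0.11 with finer clustering) over 37 in aerocyte-like cells. Tek stood at 355 and 336 CPM in general capillary-like cells. Calcrl, a receptor of adrenomedullin, was lower in both classes, at 1215 and 1003 CPM and at 1340 and 913 CPM, as was the endothelin receptor gene Ednrb, at 105 and 75.6 CPM and at 763 and 466 CPM. Ackr3, a scavenger receptor of chemokines, was higher, at 276 and 402 CPM and at 121 and 195 CPM. Kdr, the main VEGF receptor gene, was at 798 and 1258 CPM in general capillary-like cells (log2 ratio 0.66, 0.61 to 0.70) and at 2267 and 3024 CPM in aerocyte-like cells (0.42, 0.34 to 0.49). Kdr lies in a chromosome 5 segment whose genes had a median log2 ratio of 0.50 and 0.49 in these classes. Relative to that median Kdr was at 0.16 and -0.07. Aerocyte-like cells also had more Slit2 (59.4 and 133 CPM, a log2 ratio of 1.16 that was 0.12 with cells thinned to 1 depth), Dll4, a Notch ligand gene (161 and 249 CPM), and Plxna2 (188 and 302 CPM).

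The capillary endothelial-like cells of the cKO library had higher interferon response genes, higher TGF-beta and BMP targets and lower antigen presentation genes. The interferon list had a median of 0.34 in general capillary-like cells, with 18 of 21 genes higher, and 0.59 in aerocyte-like cells, with 13 of 14 higher. Isg15, a ubiquitin-like interferon product, was at 84.3 and 157 CPM in the former and 48.9 and 101 CPM in the latter. Irf7 was at 27.6 and 48.9 CPM and at 20.1 and 54.7 CPM, against a median log2 ratio of -0.48 in the other classes. The same list had a median of -0.03 in pericyte-like cells. TGF-beta and BMP targets had medians of 0.26 (percentile 100), with 12 of 17 genes higher, and 0.19 (percentile 98.6), with 12 of 14 higher. The general capillary-like median was 0.15 with each library clustered alone. Ccn1 was at 194 and 308 CPM in general capillary-like cells. Ccn2, a matricellular growth factor gene, was at 36.4 and 72.3 CPM in general capillary-like cells and 30.6 and 217 CPM in aerocyte-like cells, a log2 ratio of 2.82 (2.31 to 3.38). Antigen presentation genes had medians of -0.60 and -0.34, with H2-K1 at 1186 and 679 CPM in general capillary-like cells and 731 and 529 CPM in aerocyte-like cells. H2-K1 was lower elsewhere too, with log2 ratios of -0.93 in alveolar fibroblast-like, -0.73 in adventitial fibroblast-like and -0.25 in alveolar type 1-like cells. In general capillary-like cells the class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 were at -1.85, -1.51, -1.50 and -1.48. Coarser clustering put these 4 genes at -0.36, -0.59, -0.53 and -0.17. Angiogenic and tip genes were at a median of 0.27 (percentile 99.95) in aerocyte-like cells, which was 0.00 with cells thinned to 1 depth, and 0.06 in general capillary-like cells.

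By size, Fabp4, a fatty acid carrier gene, was the lowest eligible gene of general capillary-like cells that was not held by 1 cell, at 219 and 72.5 CPM, followed by Stmn2 and the heat shock gene Hspa1b. Gdf15 (59.9 and 151 CPM), Gm42047, Cdkn1a (595 and 1106 CPM), Isg15 and the sulfatase gene Sulf2 were the highest. S100a9 and S100a8, neutrophil genes, ranked lowest there because 1 control cell held 829 of 834 and 607 of 617 UMIs. In aerocyte-like cells the non-coding gene 9530026P05Rik, H2-Q7, Hs3st1, Arhgef10 and Enpp2 were lowest, and Ccn2, Tnfrsf12a, Olfml2b, Tbc1d1 and Irf7 highest.

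Several differences were shared by all 14 classes compared. The p53 target list had a median above 0 in 14 of 14 classes, from 0.13 to 0.80, and from 0.13 to 0.52 over the 9 classes with under 10 CPM of Foxf2 in both libraries. The immediate early list had a middle value of 0.03 over the classes, with medians from -0.35 to 0.29. Txnip, an inhibitor of thioredoxin, and 9530026P05Rik were lower in all 14, with median log2 ratios of -0.96 and -1.33, as was H2-D1 with -0.66. Pdgfrb (ENSMUSG00000024620, chromosome 18, 61045150 to 61085061) was higher in all 14, with a median of 1.32. It was at 103 and 276 CPM in adventitial fibroblast-like cells, 173 and 480.5 CPM in smooth muscle-like cells and 16.2 and 34.2 CPM in alveolar fibroblast-like cells.

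**Figure D4:**
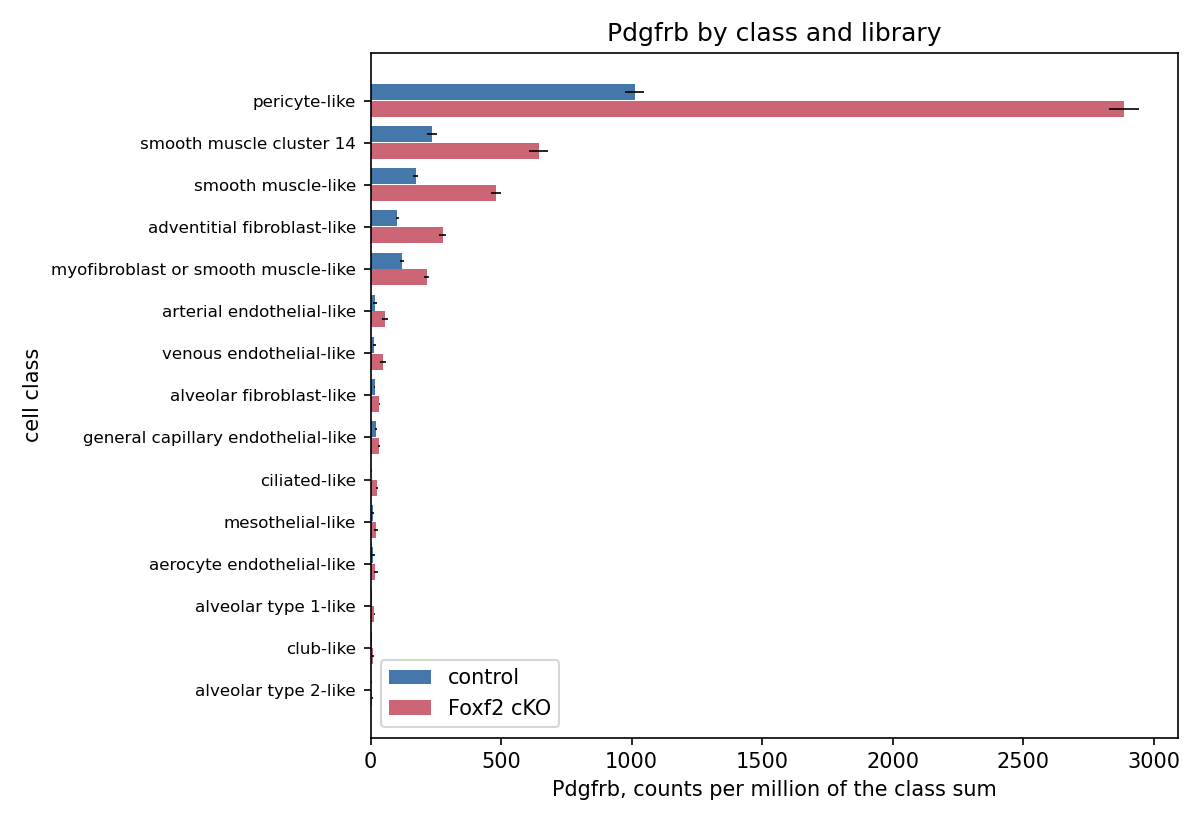
Pdgfrb in CPM (horizontal axis) by class (vertical axis) in the control and Foxf2 cKO libraries, 1 library each, with exact Poisson 95% intervals as bars. Pericyte-like cells stood at 1012 and 2884 CPM, and smooth muscle-like cells at 173 and 480.5 CPM.

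Genes of chromosome 5 between 64 and 78 Mb (mm10) were higher together in the cKO library. Of 805 windows of 2 Mb across the genome, 5 had a median log2 ratio of at least 0.4, and all 5 lay there. The segment's median was 0.46 (0.40 to 0.54) in pericyte-like cells, with 54 of 57 genes higher, against -0.06 for the rest of chromosome 5. It lay between 0.44 in alveolar type 2-like cells and 0.69 in club-like cells over the 14 classes. Besides Kdr, the segment holds Pdgfra, Kit, Hopx, Limch1, Ugdh, Srp72 and Tbc1d1. Pdgfra, the receptor of alveolar myofibroblast progenitors, was lower in the myofibroblast and smooth muscle class even so, at 193 and 109 CPM, a log2 ratio of -0.82 that lay -1.31 from the segment's median in that class. With finer clustering, a myofibroblast-like cluster with Pdgfra and Cyp2e1 among its top genes held 117 control and 30 cKO cells, so this value can follow a subset of cells too. This search by position was chosen after the data were seen.

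**Figure D5:**
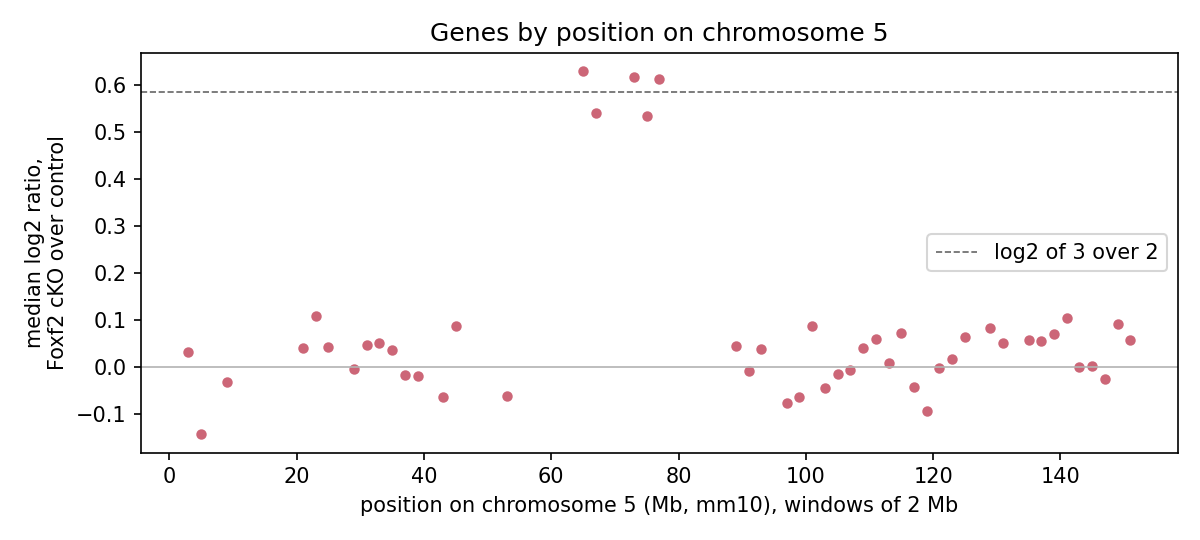
Median log2 ratio of cKO over control (vertical axis) of the genes in each 2 Mb window of chromosome 5 (horizontal axis, Mb), from classes with under 10 CPM of Foxf2, 1 library per group, for windows with at least 5 measured genes. Windows between 64 and 78 Mb stood at 0.53 to 0.63, near the log2 of 3 over 2 at 0.59 (dashed line).

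Other mesenchymal classes kept most of their Foxf2 and differed in other genes. In adventitial fibroblast-like cells, the matrix genes Thbs4 (55.6 and 4.67 CPM), Hmcn2 (56.1 and 9.05 CPM) and Cilp (80.5 and 14.8 CPM) were lowest, followed by Txnip and 9530026P05Rik, and Dcxr (26.7 and 71.6 CPM), Cdkn1a, Pbdc1, Ugdh and Ak1 highest. With each library clustered alone, Thbs4, Hmcn2 and Cilp were top genes of a separate cluster of 79 control cells that had no counterpart in the cKO library, so their values can follow a subset of cells. In alveolar fibroblast-like cells, Sfrp1, a Wnt antagonist gene, was at 131 and 54.9 CPM, among the lowest with 9530026P05Rik, Gm13889, Txnip and Klhl24. Dcxr, Gm42047, Mpp7, Cdkn1a and Thyn1 were highest there. In the myofibroblast and smooth muscle class, Cyp2e1, Txnip, the ubiquitin ligase gene Fbxo32, Vsnl1 and Fmo2 were lowest, and Scx, a tendon transcription factor gene (99.3 and 236 CPM), Lrrc15, Dcxr, Alkal1 and Srp72 highest. In smooth muscle-like cells, the growth factor gene Ptn (66.7 and 8.43 CPM), Gas1, Angptl4, Txnip and Kirrel3 were lowest, and Pdgfrb, Igfbp2 (29.2 and 77.2 CPM), Pde10a, Scx and Gm42047 highest. Mesothelial-like cells had under 10 CPM of Foxf2 in both libraries and are not counted among these classes. In them, Prg4, the lubricin gene (121 and 27.8 CPM), Cxcl13, Calca and Saa3 were among the lowest. Nrgn (12.3 and 114 CPM), Thbs2 (17.2 and 119 CPM), Gng13, Fabp3 and Fabp5 were highest.

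The groups also differed in sex. Xist, expressed from the inactive X chromosome of females, had 24 UMIs in control and 57295 in cKO cells kept, and the Y-linked gene Ddx3y 7336 and 3, so sex and genotype cannot be told apart here.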

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

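All tests in this part were chosen only after the results were seen. Genes of chromosome 5 between 64 and 78 Mb were higher in the cKO library in all 14 classes compared. Loss of Foxf2 in the same cells was argued against by the 9 classes with under 10 CPM of Foxf2, where the lowest median log2 ratio of the segment, chosen in the other classes, was 0.44 (0.34 to 0.53). Strain variants with large effects that act gene by gene would widen the spread of the segment's ratios, but their interquartile range was 1.00 times that of all other genes (median of 14 classes, 0.55 to 1.27). It was 1.24 times in alveolar fibroblast-like cells, the class with most UMIs. Genes with as few as 100 UMIs were used, and counting error widens both spreads. Smaller effects of such variants could therefore be missed and stay open. An extra copy of the segment in the cKO animals stays open. The lowest median in the 5 classes not used to choose the segment was 0.46 (0.40 to 0.54). In 3 of 14 classes the interval lay below 0.585, the log2 of 3 over 2. These were pericyte-like cells, alveolar type 2-like cells and the myofibroblast and smooth muscle class. Their medians over all genes were also the lowest, at -0.049, -0.055 and -0.065, and were not taken off. Taking each class's median off would leave the upper bounds in pericyte-like (0.535) and alveolar type 2-like cells (0.526) just under 0.585. It would lift that of the myofibroblast and smooth muscle class (0.564) above 0.585. That of aerocyte-like cells (0.592, with a median over all genes of 0.016) would fall below it. The shift thus does not account for the shortfall in every class, and these intervals do not settle whether there is an extra copy. DNA was not analysed here, and a carried transgene or a variant that acts on the whole segment was not tested.

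Pdgfrb was higher in the cKO library in all 14 classes compared, with log2 ratios from 0.55 to 2.82. With all UMIs of the pericyte gene Cox4i2 taken as free RNA, such RNA from pericyte-like cells could bring at most 40.7% (upper bound 46.9%) of the difference in any of the 4 other mesenchymal classes, which argues against it there. It could bring the whole difference in 4 of 8 endothelial and epithelial classes, or 7 at the upper counting bound, and stays open in these. Loss of Foxf2 in the same cells was argued against as the whole cause by the largest smooth muscle-like cluster, where Foxf2 was at 12.8 and 12.03 CPM and the ratio of Pdgfrb was 1.46 (1.31 to 1.60). By the same limit, free RNA could bring at most 44.1% (upper bound 49.6%) of the Pdgfrb difference in this cluster. An added Pdgfrb sequence carried by the cKO animals, such as a driver transgene, could raise it everywhere. Over the 4 classes with at least 100 CPM the ratios ranged over 0.68, from 0.83 to 1.51, which leaves this open because the driver is not given in the sources used here.

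Contractile genes were higher in pericyte-like cells of the cKO library. Free RNA from smooth muscle-like cells was argued against, since the difference in summed contractile CPM was 7.69 times the largest difference in an endothelial or epithelial class, and 1.74 times the highest sum there. An origin in only the 1% of cells with most UMIs of each gene was argued against by a list median of 0.38 without them. A larger share of cells of another class could not be detected in this way and stays open. Loss of Foxf2 in the same cells may explain the pattern, but it cannot be told apart from a cause shared by mesenchyme or by more classes. Of 4 other mesenchymal classes 2 had medians above 0.2, and the largest smooth muscle-like cluster was at 0.13. Outside mesenchyme, summed contractile CPM was higher too, as in arterial-like (1004.7 and 1434.7) and ciliated-like cells (758.8 and 1188.1). Of the 14 classes compared, only alveolar type 2-like (730.4 and 696.6) and club-like cells (752.9 and 562.2) had a lower sum. With each library clustered alone the median was 0.04, so it also depends on which cells are called pericyte-like.

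Signals outside the comparisons were seen in the cKO library. The unnamed clusters, left out of the gene comparisons, held 22.2% of its cells against 12.3% in the control library, and Pdgfrb stood at 33.3 CPM in them against 10.4 CPM. Xist, left out of the named genes, had 57295 UMIs in the cKO and 24 in the control library. Sex is thus confounded with genotype, and no difference above is free of it.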

How the results depend on the processing

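The alternatives that left out the 1% of cells with most UMIs of a gene, genes of the chromosome 5 segment, or the smaller pericyte-like cluster were chosen only after the results were seen. No paired analysis was possible because there was 1 library per group, and no result had a test whose threshold could be crossed. Foxf2 was lower in pericyte-like cells under every alternative tried, with log2 ratios from -2.29 to -1.67. Over all alternatives, 2478 values of genes stayed within their counting interval, 246 moved beyond it and 32 were counted as reversed. For list medians the numbers were 994, 33 and 10, and for shares 25 and 11 moved. Values not counted as reversed could change sign too, so 32 and 10 are not all changes of direction. In pericyte-like cells, ligands went from -0.14 to 0.057 when thinned to 1 depth. Notch targets there went from 0.18 to -0.285 with each library clustered alone. Values below are log2 ratios, with the main value first, and the cause was not tested.

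With each library clustered alone, pericyte-like cells gave contractile 0.34 to 0.038, TGF-beta and BMP targets 0.26 to -0.10, inflammation 0.15 to -0.13, cell cycle -0.30 to 0.99 and immediate early 0.11 to -0.026. Among genes there, Foxf2 went from -2.12 to -1.67, Aurkb from -0.62 to 1.84, Bub1 from -1.33 to 0.53, Ccn2 from 0.36 to -0.10, Ccn5 from 1.02 to -1.58, Map3k7cl from 1.00 to -1.18, Pdgfra from -1.32 to 1.38, Prss23 from 1.18 to -1.14, Ptgs2 from 1.14 to -0.45, Rrm2 from -0.78 to 0.82, Saa3 from -1.23 to 0.18, Slit3 from 0.45 to -1.25, Tgfbi from -2.30 to 0.64 and Tk1 from -0.47 to 1.505. General capillary-like cells gave contractile 0.24 to 0.038, pericyte identity -0.05 to -0.51, collagen 0.21 to -0.053, cell cycle -0.09 to -2.30 and mitochondrial genes -0.17 to 0.022. Their share was 5.44% in the control and 4.67% in the cKO library, against 6.78% and 6.41%.

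With the mean of each cell's CPM, pericyte-like cells gave ligands -0.14 to 0.081, capillary identity -0.23 to 0.16, mitochondrial genes -0.10 to -0.001 and Notch3 0.18 to -0.037. General capillary-like cells gave mitochondrial genes -0.33, surfactant 0.00 to 0.33 and Meox2 0.55 to -0.045, and aerocyte-like cells mitochondrial genes -0.33 to -0.55, alveolar type 1 genes 0.34 to -0.042 and Hspg2 1.00 to -0.028.

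With called doublets kept, pericyte-like cells gave inflammation -0.15 and surfactant 0.59 to 0.11. General capillary-like cells gave contractile 0.00, alveolar fibroblast identity 0.30 to -0.003, collagen -0.16, Actg2 0.55 to -0.051, Il33 1.11 to -0.18, Lox 0.86 to -0.36 and shares of 8.26% and 7.60%, and aerocyte-like cells collagen 0.14 to 0.398.

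Thinned to 1 depth, pericyte-like cells gave cell cycle -0.38, Cnn1 1.16 to -0.10, Flt4 2.49 to -0.10 and Hhip -1.32 to 0.55. General capillary-like cells gave alveolar fibroblast identity 0.023, cell cycle 0.006, surfactant 0.45, Egr2 1.42 to -0.01, Meox2 -0.31, Slc7a10 2.31 to -0.01 and Tk1 -0.29 to 0.036. Aerocyte-like cells gave collagen 0.23, angiogenic genes 0.27 to 0.002, oxidative stress 0.06 to -0.12, mitochondrial genes -0.52, vasoregulation 0.025 to 0.255 and Cxcl1 2.16 to -0.042.

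Without the 1% of cells with most UMIs, cell cycle was -0.46, Cxcl10 1.18 to -0.50 and Tff2 -5.20 to 0.90 in pericyte-like cells, alveolar fibroblast identity 0.77, surfactant 0.56 and Ccl7 3.34 to -0.013 in general capillary-like cells, and Cxcl2 2.75 to -0.16 and Rsad2 3.50 to -0.16 in aerocyte-like cells. Resolution 0.5 gave general capillary-like contractile 0.55, mitochondrial -0.11, surfactant 0.78 and shares of 13.7% and 18.2%. Resolution 2 gave alveolar fibroblast identity 0.14 and shares of 7.93% and 7.25% there, and receptors -0.04 to -0.11 and shares of 3.08% and 3.91%, against 1.92% and 1.94%, in aerocyte-like cells. At least 2000 UMIs gave a general capillary-like cKO share of 7.28%. At most 5% mitochondrial UMIs, which limits these genes by construction, gave aerocyte-like mitochondrial genes -0.12. TMM factors gave mitochondrial genes -0.045 and DESeq2 factors -0.046 in pericyte-like cells.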

Other observations

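The genes in this part were chosen only after their values were seen. Beside the chromosome 5 segment, some genes differed in the same direction in every class measured, at least 12 of 14, with a median of at least 1.5-fold. Lower in the cKO library were the interferon-induced membrane protein gene Ifitm1, with a median log2 ratio of -0.96 and 662 and 334 CPM in pericyte-like cells, Stmn2 (-1.10), Fbxo32 (-1.11), Angptl4 (-0.93) and Hspa1b (-0.84). Higher were the atrial and cardiac muscle genes Myl7 (1.78) and Actc1 (0.91), the squalene epoxidase gene Sqle (0.80) and the X-linked p53 target Eda2r (0.70). Myl7 was at only 2.29 and 8.24 CPM in pericyte-like cells, and Actc1 at 24.5 and 35.1 CPM. Myl7 was also a top gene of a shallow unnamed cluster with 512 control and 892 cKO cells. Whether free RNA brings these muscle genes to the classes was not tested.

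In the largest smooth muscle-like cluster, where Foxf2 was low and nearly alike in both libraries, the metallothionein gene Mt1 (240.4 and 64.0 CPM), Tcp11l2, Lgals3, Slc10a6 and Pclo were lowest. Igfbp2 (15.5 and 136 CPM), Pdgfrb, Fdps and Ppa1 were among the highest, and Grip1 ranked above them because 1 cKO cell held 161 of its 171 UMIs. Chondrocyte-like cells made up 0.863% of control and 0.132% of cKO cells, a difference that dissection of large airways can set.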
